A study of Homo sapiens with 21 samples.

How the data were processed

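The deposited data were 21 RSEM gene tables, 1 for each of 3 libraries of the 7 SUM149PT lines. Messenger RNA was selected by its poly(A) tail and sequenced from one end. Per the submitters' processing notes, the authors made reads with bcl2fastq 2.20.0.422, trimmed them with cutadapt 2.4, aligned them to hg38 with STAR 2.7.2b and counted them with RSEM 1.3.2; the annotation release and the strand setting were not given. Per the file headers, the deposited values were expected counts, TPM and effective lengths for each gene. The expected count is the number of reads the authors' RSEM run assigned to a gene, and 7.4 to 8.6% of the values in a library were not whole. The TPM the authors deposited scales those counts by effective length, in bases, and by library. Tables held 60617 genes, 60596 with a symbol and 58542 in GENCODE 29, which gave positions and gene types. No table held columns of other samples.

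Expected counts were rounded and tested in R 4.3.3 with edgeR 4.0.16 (quasi-likelihood F-test, robust, TMM scaling, low-count filter by line), all 21 libraries in 1 fit with 1 mean per line and 14 residual degrees of freedom. The filter kept 18632 genes, normalization factors were 0.92 to 1.13, and the common biological coefficient of variation was 0.34 (0.24 with the library set as a term, 11 residual degrees of freedom). A gene was called at a BH-adjusted p under 0.05 within its contrast. There were 15 contrasts and 3 lists of genes called with one sign in several contrasts. Nothing in the labels says that the libraries of a line came from separate cultures, so the p-values measure only the spread between these libraries. Totals were 24.6 to 48.1 per library, in units of 1e6 counts. On data simulated from the EM1 and E libraries, edgeR called 16.4% of 67 genes changed 2-fold, 79.1% of 67 changed 4-fold and 95.5% of 66 changed 8-fold, with 8 unchanged genes called. The limma-voom test called 20.9, 79.1 and 93.9% (17 unchanged genes) and DESeq2 34.3, 89.6 and 98.5% (44 unchanged genes). Camera on the same data gave 8.16e-26 for a list built to change and 0.619 for an unchanged one. Each gene was drawn independently and without a difference between library sets. These runs therefore cannot show how camera does where the genes of a list vary together.

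There were 19 fixed gene lists with 352 genes, all with a row in the tables, tested with camera (limma 3.58.1) on voom values with a preset correlation of 0.01 in the 5 clone contrasts against E, with BH adjustment over all lists and contrasts together. The core-binding factor list was written from what was known of the study. Of the tests 39 were called. Counts of called list genes used p-values adjusted over all genes, and a second count used p-values adjusted over the list alone. Levels are TPM, which rest on effective lengths, while tests rest on counts, so the ratio of levels can differ from the tested fold. The lists, contrasts, tests, alternatives and the rule for named genes were fixed before the data were examined. That rule took called genes with every library of one group above every library of the other, a mean CPM of at least 1 and a symbol of a protein-coding gene. It took the 10 largest changes in each direction for both M clones, the 8 largest for all 3 EM clones and for EM clones apart from E and M, 5 for single contrasts, 3 against Parental, and any gene of a fixed list. Of the genes this rule allowed, the text favours those whose calls held under the alternatives, a choice made after their values were seen.

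Alternatives chosen before the data were examined were no low-count filter, a stricter filter (mean CPM of at least 1), DESeq2 1.42.0 size factors, the DESeq2 Wald test, limma-voom, limma-trend on TPM, a log2 fold of at least 1, the libraries of the compared lines only, the replicate number as a block, each library left out in turn, and for lists fry and an estimated correlation. Chosen after seeing the data were the library set as a term, the long set alone, mean effective length as a covariate and list tests with the set term. The TPM test worked on log2(TPM + 1) and kept genes with a mean TPM of at least 1, so its list counts can cover fewer genes. Not every pair of libraries sharing a replicate number deviated together, so the numbers were not taken as pairs: 40 of 63 same-number pairs correlated above 0.1 (median 0.23, range -0.43 to 0.92), and 12 of 21 libraries correlated best with their own number. Replicate 3 of every clone other than E also shared the short set, so a batch shared by number is not excluded. Every pair was above 0.1 in M1 against E, EM2 against EM1, EM3 against EM2 and M2 against M1, where the block gave 7924, 1984, 1603 and 8609 calls. Tables were read with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1, and figures drawn with matplotlib 3.10.9. Some results are not reported here because they are withheld for evaluation.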

Results

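Messenger RNA was sequenced from 7 lines of SUM149PT, an inflammatory breast cancer cell line that lacks estrogen and progesterone receptor protein. They were the uncloned parental line (Parental) and 6 clones grown from single cells, which the submitters named E, EM1, EM2, EM3, M1 and M2. The series title places the EM clones in an intermediate state between epithelial and mesenchymal cells. Each line had 3 libraries, 21 in all, without any treatment. Totals of expected counts, in units of 1e6 and in the order of replicates 1 to 3, were 44.2, 48.1 and 48.1 for E, 35.4, 27.6 and 41.7 for EM1, 44.7, 32.2 and 42.7 for EM2, and 40.7, 38.1 and 42 for EM3. They were 37.5, 46.6 and 42.4 for M1, 37.8, 25 and 47.7 for M2, and 36.2, 24.6 and 27 for Parental. The 18 clone libraries fell into 2 sets by mean effective length, a split seen in the files and not named in the labels. The short set held all 3 libraries of E and replicate 3 of every other clone (8 libraries, 1971 to 2038 bases). The long set held the other 10 (2121 to 2238 bases), and Parental lay between (2053 to 2117 bases). Counts of called genes between clones are therefore given also with the set as a term in the model, an alternative chosen after seeing the data. The list levels per line have no such term. Levels below are TPM, as mean ± SD over the 3 libraries of a line (n = 3).

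The level of the fixed gene lists in each line asks how far each clone lies from an epithelial to a mesenchymal state. Genes of epithelial identity averaged 6.07 ± 0.04 in E on the log2(TPM + 1) scale, 5.71 ± 0.36 in EM1, 5.31 ± 0.26 in EM2, 5.37 ± 0.21 in EM3 and 5.65 ± 0.35 in Parental, and 1.71 ± 0.09 in M1 and 1.35 ± 0.08 in M2. Basal and squamous genes, which mark the outer layer of breast ducts and stratified epithelia, went from 6.98 ± 0.14 in E through 5.79 ± 0.61, 5.35 ± 0.76 and 5.57 ± 0.40 in EM1, EM2 and EM3 and 5.84 ± 0.35 in Parental to 3.36 ± 0.13 in M1 and 1.76 ± 0.10 in M2. Mesenchymal genes stood at 3.33 ± 0.06 in E, 3.36 ± 0.22 in EM1, 4.19 ± 0.14 in EM2, 4.12 ± 0.27 in EM3, 6.07 ± 0.18 in M1, 4.38 ± 0.22 in M2 and 3.20 ± 0.27 in Parental. The libraries of a pair of lines did not overlap in 13, 15 and 15 of the 21 pairs for the 3 lists, where chance gives 10% for 3 libraries against 3. For a single pair of lines an exact permutation p cannot lie below 0.10, and no p is given. The lower epithelial mean of EM1 came from replicates 1 and 2 of the long set (5.498 and 5.513), while replicate 3, in the short set with E, stood at 6.122, above all 3 E libraries (6.024 to 6.098). Basal levels were also highest in replicate 3 of EM1, EM2 and EM3 (6.382, 6.216 and 6.01, against 4.83 to 5.815 in their long-set libraries). These still lay below E (6.815 to 7.059), so part of the basal drop in the EM clones can come from the set. Replicate 3 was not the highest in M1 or M2. Across 11124 genes, the first principal component (57.1% of the variance) set M2 apart, the second (15.9%) set M1 apart, and the third (10.3%) separated the library sets.

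**Figure D1:**
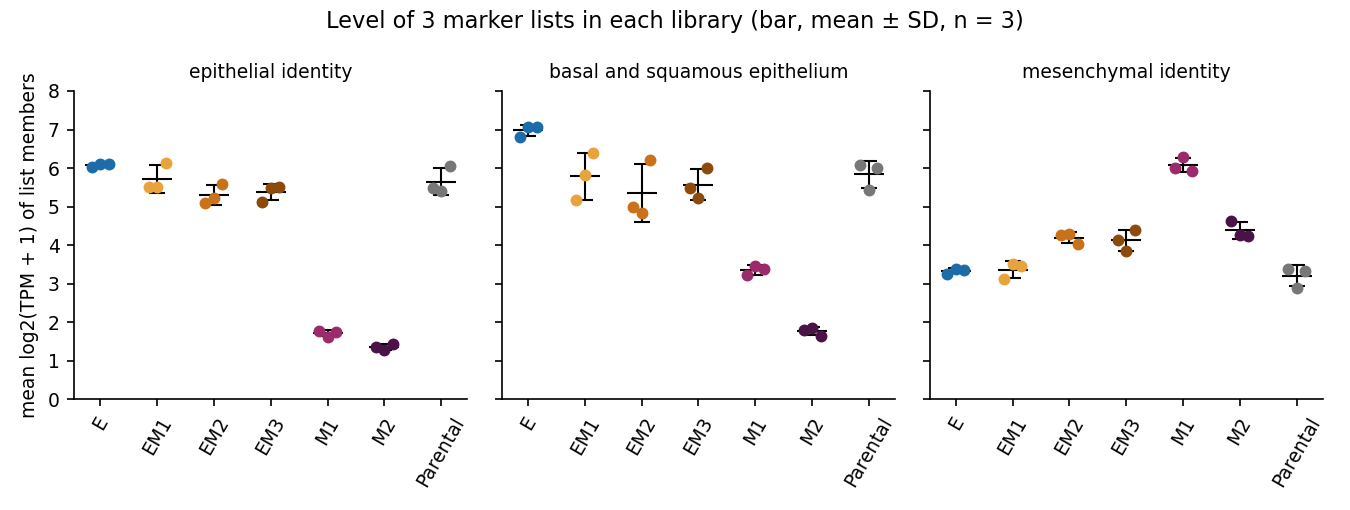
Mean log2(TPM + 1) of the epithelial, basal and mesenchymal lists, one point per library and a bar at the mean ± SD of each line (n = 3). Epithelial levels of the EM clones (5.31 to 5.71) lie near E (6.07), far above M1 (1.71) and M2 (1.35).

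**Figure D2:**
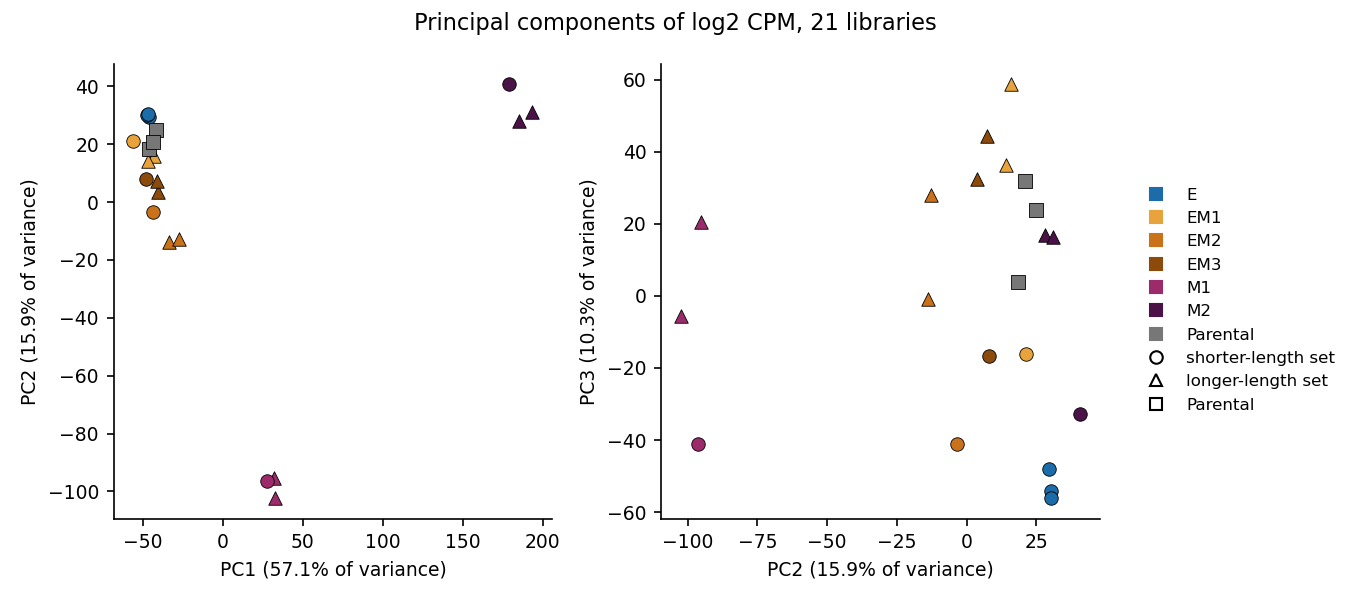
Principal components of log-CPM over 11124 genes, one point per library, axes labelled with their percent of the variance. Component 1 holds 57.1% and component 2 holds 15.9%.

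EM1 against E asks what an intermediate-named clone differs in from the epithelial-named one. Vimentin (VIM), the intermediate filament of mesenchymal cells, rose from 13.8 ± 1.54 TPM in E to 706 ± 98.5 in EM1 (edgeR, BH-adjusted p = 1.82e-08). Keratin 8 (KRT8), a filament protein of simple epithelia, fell from 4568 ± 361 to 1330 ± 831 (edgeR, BH-adjusted p = 0.00298). The basal keratins KRT5 (778 ± 46.9 to 159 ± 72.2) and KRT14 (22 ± 0.98 to 3.10 ± 1.22) fell too. The adherens junction gene CDH1 (E-cadherin) measured 108 ± 17.3 and 46.8 ± 27.6 and did not pass the test (edgeR, BH-adjusted p = 0.0934). It passed with limma-voom (adjusted p = 0.032), the EM1 and E libraries alone (0.0255), the replicate block (0.0107) and no low-count filter (2.92e-06), and without EM1 replicate 3 (0.0369) or M2 replicate 3 (0.0437). It did not pass with the library set as a term. CDH1 stood at 35.1 and 27.0 in EM1 replicates 1 and 2 of the long set. Replicate 3, in the short set with E (87.5 to 118), stood at 78.4. Enzymes that make cholesterol rose, among them HMGCS1 from 12.1 ± 3.98 to 240 ± 128, SQLE from 12.3 ± 1.31 to 140 ± 43.3 and IDI1 from 10.1 ± 1.22 to 266 ± 106. Genes that interferon induces fell, with the ubiquitin-like modifier ISG15 at 19.3 ± 0.94 in E and 3.72 ± 0.07 in EM1. E was also above Parental (5.92 ± 3.72; edgeR, BH-adjusted p = 0.00124).

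Among the fixed lists in EM1, 8 of the 30 epithelial genes fell, the surface mucin MUC1 among them, and 2 rose, the transcription factor GRHL2 and the lipid enzyme CDS1 (the same counts adjusted over the list alone and with the library set as a term). Camera placed that list below other genes (BH-adjusted p = 0.00191, and adjusted p = 0.361 with an estimated correlation). Of 22 basal genes 9 fell (11 adjusted over the list alone, 8 with the set term). Camera gave a BH-adjusted p = 1.49e-06, and adjusted p = 0.249 with an estimated correlation. Unlike VIM, the mesenchymal list did not rise: of 31 genes 4 were higher and 5 lower. Adjusted over the list alone these were 5 and 7, and with the set term 4 and 6. Camera did not call that list (BH-adjusted p = 0.444). Interferon response genes fell as a group, 14 of 18 measured (15 adjusted over the list alone, 16 with the set term, 6 with TPM). The camera test gave a BH-adjusted p = 6.15e-12, and adjusted p = 0.00269 with an estimated correlation. Cholesterol synthesis genes rose in 11 of 15 cases (12 adjusted over the list alone, 15 with the set term). By camera this list had a BH-adjusted p = 1.12e-09, and adjusted p = 0.173 with an estimated correlation. For antigen presentation, 7 of 12 genes fell, PSMB9 of the immunoproteasome among them (7 adjusted over the list alone, 6 with the set term, 3 with TPM). For these genes camera gave a BH-adjusted p = 0.000309, and adjusted p = 0.173 with an estimated correlation. The count of 8 epithelial genes was 3 without EM1 replicate 1 and 5 without EM1 replicate 2, and that of 9 basal genes 3 and 4 without the same libraries. The 14 interferon genes became 9, 9, 9 and 8 without E replicates 2 and 3 and EM1 replicates 1 and 2, and the 7 antigen presentation genes 3 without each of these.

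EM1 differed from E in 3341 of 18632 genes (edgeR, BH-adjusted p under 0.05), 1834 higher and 1507 lower. Genes at the extremes included TRMT10B, a tRNA methyltransferase gene with no count in E and 2.04 ± 0.61 TPM in EM1, and the zinc finger gene ZNF43 (0.01 TPM against 2.55 ± 1.07). CMBL, TP53I11 and CRMP1 had no count in the 3 libraries of EM1 and stood at 1.35 ± 0.21, 1.88 ± 0.04 and 1.02 ± 0.11 in E. With the library set as a term 3417 genes were called (1847 higher, 1570 lower), and 79.1% of the 3341 were called again with the same sign. Higher genes made up 54.9% of the calls, and 74.2% when TPM was tested in place of counts. The 3341 fell to 2036, 1881 and 1890 without E replicate 1, 2 or 3 and to 1812 and 2009 without EM1 replicate 1 or 2.

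In EM2, VIM rose to 963 ± 435 TPM against 13.8 ± 1.54 in E (edgeR, BH-adjusted p = 6.86e-09), and ZEB1, a repressor of epithelial genes, to 1.33 ± 0.68 against 0.17 ± 0.15 (edgeR, BH-adjusted p = 0.00025). Keratin 19 (KRT19), a keratin of simple epithelia, fell from 852 ± 49.7 to 41.2 ± 19.4, the tight junction gene OCLN from 25.7 ± 2.31 to 9.51 ± 2.79, and the basal keratin KRT15 from 32.1 ± 4.94 to 1.64 ± 0.42. Collagen VI genes of the extracellular matrix rose, COL6A3 from 2.74 ± 0.54 to 49.3 ± 9.06 and COL6A2 from 7.04 ± 1.41 to 77.6 ± 23.8. Interferon-induced IFI27 fell from 264 ± 58.6 to 0.36 ± 0.27, and ISG15 to 4.57 ± 0.77.

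By list, 11 of the 30 epithelial genes fell in EM2 and 2 rose (16 and 2 adjusted over the list alone, 11 and 1 with the set term). As a group they had a camera BH-adjusted p = 3.15e-07, and adjusted p = 0.173 with an estimated correlation. Without E replicates 1, 2 and 3 and EM2 replicates 1 and 2 the 11 became 6, 5, 5, 4 and 5, and the 2 became 1 without E replicates 2 and 3 and EM2 replicates 1 and 2. Basal genes fell in 7 of 22 cases (13 adjusted over the list alone, 9 with the set term, 14 with limma-voom and without EM2 replicate 3, 11 with DESeq2 and with TPM). Camera gave a BH-adjusted p = 1.12e-09, and adjusted p = 0.173 with an estimated correlation. The mesenchymal list rose, with 13 of 31 genes higher, FAP, MMP2 and VCAN among them (13 adjusted over the list alone and with the set term, 8 without E replicate 1 or EM2 replicate 1; camera, BH-adjusted p = 0.000621, and adjusted p = 0.249 with an estimated correlation). The cadherin gene CDH11 fell from 3.25 ± 0.33 to 0.14 ± 0.10. Interferon response genes fell in 12 of 18 cases (14 adjusted over the list alone, 13 with the set term, 6 with TPM). The camera test gave a BH-adjusted p = 1.41e-11, and adjusted p = 0.00269 with an estimated correlation. For antigen presentation, 5 of 12 genes fell, among them the immunoproteasome genes PSMB8 and PSMB9 (7 adjusted over the list alone, 4 with the set term, 3 with TPM and without any 1 library of E or EM2). By camera this list had a BH-adjusted p = 0.00168, and adjusted p = 0.173 with an estimated correlation. Hypoxia and glycolysis genes rose in 4 of 16 cases (4 adjusted over the list alone, 6 with the set term, and 2, 1, 1 and 1 without E replicates 1, 2 and 3 and EM2 replicate 2). For these genes camera gave a BH-adjusted p = 0.0118, and adjusted p = 0.266 with an estimated correlation.

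EM2 against E gave 2588 called genes (edgeR, BH-adjusted p under 0.05), 1294 higher and 1294 lower. At the extremes, CAAP1 (a caspase activity regulator) had no count in E and 5.80 ± 0.60 TPM in EM2, and its neighbour PLAA (a ubiquitin-binding protein) went from 0.05 ± 0.05 to 15.2 ± 2.08. The cell cycle gene G0S2 went from 57.4 ± 14.7 to 0.02 ± 0.02, and the small heat shock gene HSPB8 from 1.22 ± 0.17 to no count. With the set term 3404 genes were called (1663 higher, 1741 lower), 84.9% of the 2588 among them with the same sign. The EM2 and E libraries alone gave 4267. Higher genes made up 50% of the calls and 71.3% with TPM. Without E replicates 1, 2 and 3 the count was 1718, 1579 and 1556, and without EM2 replicates 1 and 2 it was 1608 and 1606.

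EM3 carried VIM at 1255 ± 223 TPM against 13.8 ± 1.54 in E (edgeR, BH-adjusted p = 7.47e-09) and ZEB1 at 3.38 ± 0.76 against 0.17 ± 0.15 (edgeR, BH-adjusted p = 5.09e-06). TWIST2, a helix-loop-helix factor also linked to the mesenchymal state, fell from 8.18 ± 0.49 to 3.27 ± 0.37. The tight junction genes CLDN4 (50.9 ± 9.29 to 6.24 ± 3.37) and CLDN7 (380 ± 33.1 to 136 ± 20.8) fell, as did KRT8 (to 1197 ± 886) and KRT5 (to 206 ± 71.1). HMGCS1 rose to 194 ± 74.0, SQLE to 117 ± 38.7 and IDI1 to 233 ± 125, levels close to those of EM1. ISG15 fell to 3.96 ± 1.24 and the antiviral enzyme OAS1 from 2.06 ± 0.36 to 0.07 ± 0.04.

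The epithelial list fell in EM3 with 14 of 30 genes lower and 2 higher (16 and 2 adjusted over the list alone, 12 and 1 with the set term). As a group they had a camera BH-adjusted p = 3.18e-07, and adjusted p = 0.173 with an estimated correlation. The 14 became 9 without EM3 replicate 1, and the 2 became 1 or fewer without E replicates 1 to 3, EM1 replicates 1 and 2, EM2 replicate 1, EM3 replicates 1 and 2, M1 replicate 2 or Parental replicates 1 to 3. Basal genes fell in 12 of 22 cases (13 adjusted over the list alone, 8 with the set term, and 7, 7 and 6 without E replicate 3 and EM3 replicates 1 and 2). Camera gave a BH-adjusted p = 1.65e-08, and adjusted p = 0.173 with an estimated correlation. Mesenchymal genes were higher in 10 of 31 cases, COL6A3, COL6A2 and CTHRC1 among them, and 3 were lower (10 and 4 adjusted over the list alone, 12 and 3 with the set term, 1 lower without E replicates 1 to 3 or EM3 replicates 1 and 2). The camera test gave a BH-adjusted p = 0.0397, and adjusted p = 0.478 with an estimated correlation. That call ended with the replicate block (adjusted p = 0.0715) and without E replicate 1, EM3 replicate 3 or M2 replicate 2 (0.0575, 0.221 and 0.0532). Interferon response genes fell in 9 of 18 cases (14 adjusted over the list alone, 13 with the set term, 4 with TPM). By camera this list had a BH-adjusted p = 1.12e-09, and adjusted p = 0.00481 with an estimated correlation. Cholesterol synthesis genes rose in 10 of 15 cases (12 adjusted over the list alone, 15 with the set term). For these genes camera gave a BH-adjusted p = 6.62e-09, and adjusted p = 0.205 with an estimated correlation.

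EM3 against E called 3227 genes (edgeR, BH-adjusted p under 0.05), 1744 higher and 1483 lower. Besides TRMT10B (2.23 ± 0.71 TPM) and ZNF43 (2.56 ± 0.95), the zinc finger gene ZNF441 stood at 0.28 ± 0.12 in EM3 with no count in E. EPHX2, an epoxide hydrolase, and HSPB8 had no count in EM3 and stood at 3.33 ± 1.02 and 1.22 ± 0.17 in E. With the set term 3740 genes were called (2007 higher, 1733 lower), 83% of the 3227 among them with the same sign. The EM3 and E libraries alone gave 5904. Higher genes made up 54% of the calls and 80% with TPM. Without E replicates 1, 2 and 3 the count was 2093, 2013 and 1950, and without EM3 replicates 1 and 2 it was 2021 and 2007.

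Further lists were called in the EM clones. Proliferation genes lay above other genes by camera in EM1, EM2 and EM3 (BH-adjusted p = 0.0248, 0.000254 and 0.0123), with adjusted p = 0.662, 0.476 and 0.618 with an estimated correlation and 0.221, 0.0628 and 0.181 with fry. Of the 24 members edgeR called 1, 3 and 2 higher in EM1, EM2 and EM3 (1 to 7 in EM2 with 1 library left out). The cyclin gene CCNA2 rose in EM1 (84.5 ± 44.6 TPM) and EM3 (83.8 ± 41.9) over E (12.9 ± 2.79), and the cell cycle regulator E2F1 in EM2 (27.6 ± 7.46 over 8.04 ± 1.71). With the set term the camera calls of this list ended in EM1 and EM3 (adjusted p = 0.321 and 0.251). They also ended without E replicate 3 or EM1 replicate 1 in EM1 (0.091 and 0.108) and without E replicate 3 or EM3 replicate 2 in EM3 (0.0516 and 0.0562). Antigen presentation genes lay lower in EM3 (camera, BH-adjusted p = 0.0475, and adjusted p = 0.38 with an estimated correlation). That call ended with the set term (0.16) and without E replicate 3, EM1 replicate 1, EM2 replicate 2 or 3, EM3 replicate 2, M2 replicate 2 or Parental replicate 1 (0.0634, 0.0502, 0.05, 0.0511, 0.0962, 0.0539 and 0.0528). The matrix protease list lay lower in EM1 (camera, BH-adjusted p = 0.0179, and adjusted p = 0.447 with an estimated correlation). That call ended with the set term (0.188) and without EM1 replicate 1 (0.0679), and 2 of its 3 called members were higher when TPM was tested. The list of blood, immune and endothelial markers, fixed as a check for cells a breast cancer line should lack, lay lower in EM1, EM2 and EM3 (camera, BH-adjusted p = 0.000309, 0.0317 and 0.00194, and adjusted p = 0.107, 0.269 and 0.173 with an estimated correlation). The EM2 call ended with the set term (0.266). The hemoglobin gene HBA1 of that list fell from 9.89 ± 1.14 in E to 2.79 ± 0.75 in EM1 and 3.65 ± 0.80 in EM3.

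All 3 EM clones together asked which differences from E they share. VIM and the membrane raft gene RFTN1 (0.21 ± 0.09 TPM in E and 3.96 ± 1.41, 3.90 ± 1.65 and 3.98 ± 1.36 in EM1, EM2 and EM3) were higher in each. So were the sialyltransferase ST6GAL2 (0.50 ± 0.81 against 21.6 ± 5.57, 7.35 ± 5.79 and 7.57 ± 1.18) and the ETS transcription factor FLI1 (0.04 ± 0.03 against 1.3 ± 0.07, 2.82 ± 0.86 and 1.72 ± 0.10). RUNX3, a DNA-binding subunit of core-binding factor, rose from 9.09 ± 2.50 to 21.4 ± 10.8, 31.6 ± 1.36 and 32.2 ± 12.4. G0S2, the metalloproteinase inhibitor TIMP3 and the carboxylesterase CES1, at 57.4 ± 14.7, 3.13 ± 0.34 and 28.4 ± 3.86 in E, lay at or under 0.03, 0.01 and 0.28 in the 3 clones. CES1 and TIMP3 were lower in Parental than in E as well. EM1, EM2 and EM3 against Parental called 374, 1024 and 689 genes, while E against Parental called 2040. Part of the shared differences from E can thus be particular to E, though these counts also depend on the libraries. E lies wholly in the short set. Its libraries differed less among themselves (chi-square per degree of freedom 6.96 to 25.49, against at least 65.57 in other lines). With mean effective length as a covariate the EM counts against Parental rose, to above 2040 in EM2 and EM3, as given in the closing section. In total 671 genes were higher and 531 lower in all 3 contrasts (edgeR, BH-adjusted p under 0.05 in each), 1202 together, where independent lists would share 11.9 and 8.3. With the set term the count was 1396 (751 higher, 645 lower), 970 of the 1202 among them. Simulated unchanged groups against the 3 E libraries shared no gene in 10 runs, but E's 3 libraries are too few to split, and part of the excess can come from these shared controls. The simulation drew each gene independently and held no difference between library sets, so it could not show what these would share. Higher genes made up 55.8% of the 1202, 77.4% with TPM and 43.2% with limma-voom, and the count was 751, 666 and 656 without E replicates 1, 2 and 3 and 2002 with the libraries of the compared lines alone.

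Genes that set the EM clones apart from E and from both M clones bear on whether the intermediate state has its own features. The adenylate cyclase gene ADCY1 stood at 10.7 ± 0.36, 3.52 ± 0.74 and 12.8 ± 1.82 TPM in EM1, EM2 and EM3, against 0.39 ± 0.02 in E and 0.96 ± 0.22 in M1. LPL, the lipase that hydrolyses lipoprotein triglycerides, reached 32.7 ± 2.92, 21.7 ± 2.37 and 21.3 ± 1.88, against 1.07 ± 0.39 in E, 5.45 ± 1.84 in M1 and 0.12 ± 0.16 in M2. ST6GAL2 was higher in the same 9 contrasts. On the lower side, MAGED1, a melanoma antigen family member, measured 0.16 ± 0.18, 0.27 ± 0.08 and 0.05 ± 0.02, against 4.57 ± 0.84 in E, 41.8 ± 7.41 in M1 and 9.66 ± 6.82 in M2. TIMP3 lay at or under 0.01 in the EM clones and at 3.13 ± 0.34, 7.78 ± 2.83 and 3.78 ± 1.36 in E, M1 and M2. These genes were not compared for being apart from Parental, where ADCY1 and LPL stood at 3.86 ± 1.44 and 16.5 ± 5.63, and TIMP3 had a single count in the 3 libraries. All 9 contrasts called 78 genes with one sign (edgeR, BH-adjusted p under 0.05 in each), 32 higher and 46 lower; with the set term there were 145 (75 higher, 70 lower), 72 of the 78 among them. Higher genes made up 41% of the 78 and 64.6% with TPM.

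**Figure D3:**
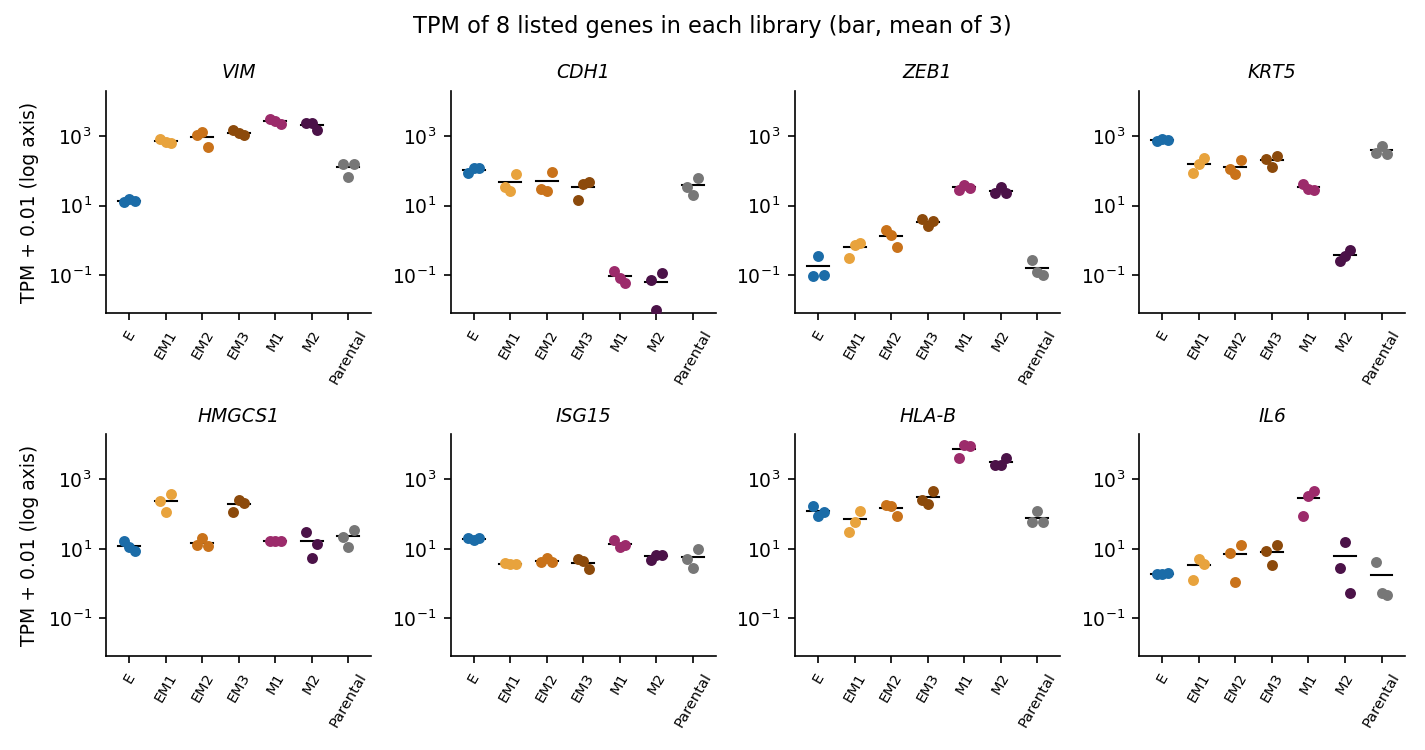
TPM + 0.01 on a log axis of 8 genes of the fixed lists, one point per library and a bar at the mean of 3, with lines on the horizontal axis. VIM rises from 13.8 in E to 2664 in M1, and CDH1 falls from 108 in E to 0.08 in M1, while HLA-B is uncertain because near-identical copies can share its reads.

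M1 against E compares a mesenchymal-named clone with the epithelial-named one. CDH1 fell from 108 ± 17.3 TPM in E to 0.08 ± 0.04 in M1 (edgeR, BH-adjusted p = 1.53e-08), the desmosome gene DSP from 56.7 ± 4.99 to 0.37 ± 0.05 and the placental cadherin CDH3 from 102 ± 7.51 to 0.33 ± 0.26. VIM rose to 2664 ± 468 and fibronectin (FN1) from 454 ± 21.8 to 4252 ± 276, collagen I (COL1A1) from 6.17 ± 0.17 to 659 ± 121 and decorin (DCN) from 46 ± 5.44 to 2001 ± 384. The transcription factors ZEB1 (33.3 ± 6.09 against 0.17 ± 0.15), ZEB2 (17.0 ± 3.15 against 2.41 ± 0.26) and PRRX1 (11 ± 5.23 against 0.22 ± 0.16) rose with them. RUNX3 reached 71.3 ± 11.5, and the signalling ligand gene WNT5A went from 5.79 ± 0.64 to 465 ± 55.3.

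Every one of the 30 epithelial genes fell in M1 (30 adjusted over the list alone and with the set term; camera, BH-adjusted p = 6.29e-27, and adjusted p = 0.00491 with an estimated correlation). So did 21 of 22 basal genes (22 adjusted over the list alone, 21 with the set term; BH-adjusted p = 2.13e-13, and adjusted p = 0.1 with an estimated correlation). Of 31 mesenchymal genes 22 rose (22 adjusted over the list alone, 24 with the set term) and 1 fell, CTHRC1. As a group they had a camera BH-adjusted p = 6.15e-12, and adjusted p = 0.0305 with an estimated correlation. Of 15 EMT transcription factors 9 rose (10 adjusted over the list alone, 9 with the set term; camera, BH-adjusted p = 0.0041, and adjusted p = 0.0512 with an estimated correlation). SOX9 fell from 36.2 ± 5.66 to 6.01 ± 1.24. Inflammatory genes rose in 10 of 20 cases (11 adjusted over the list alone and with the set term; camera, BH-adjusted p = 0.000696, and adjusted p = 0.478 with an estimated correlation). The chemokine CXCL1 went from 115 ± 5.79 to 2296 ± 183, CCL2 from 0.02 ± 0.02 to 26.1 ± 6.66 and the prostaglandin synthase PTGS2 from 12 ± 0.42 to 77.2 ± 39.7. Matrix proteases and their inhibitors rose in 8 of 17 cases (9 adjusted over the list alone, 12 with the set term; camera, BH-adjusted p = 0.00074, and adjusted p = 0.266 with an estimated correlation). The collagenase MMP13 stood at 0.11 ± 0.02 in E and 244 ± 53.4 in M1, while matrilysin (MMP7) fell from 41.5 ± 7.01 to 0.08 ± 0.03. Antigen presentation genes rose in 5 of 12 cases, among them B2M (1219 ± 63.0 to 5769 ± 1806) and the transcription regulator NLRC5 (1.77 ± 0.59 to 10.5 ± 1.5) (5 adjusted over the list alone, 6 with the set term). Camera gave a BH-adjusted p = 0.0177, and adjusted p = 0.278 with an estimated correlation.

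Interferon response genes fell in M1 in 9 of 18 cases (10 adjusted over the list alone, 12 with the set term, 2 with TPM; camera, BH-adjusted p = 0.000666, and adjusted p = 0.1 with an estimated correlation). IFI44L fell from 18.8 ± 0.75 to 3.57 ± 2.49 TPM. Hypoxia and glycolysis genes rose in 6 of 16 cases (6 adjusted over the list alone, 5 with the set term; camera, BH-adjusted p = 0.0117, and adjusted p = 0.266 with an estimated correlation). Among them were the vessel growth factor VEGFA (28.5 ± 2.10 to 264 ± 44.6) and adrenomedullin (ADM, 8.96 ± 0.58 to 123 ± 3.37). Proliferation genes lay above other genes (camera, BH-adjusted p = 0.00888, and adjusted p = 0.594 with an estimated correlation), a call that ended with the set term (0.107) and with fry (0.0583). YAP and TEAD targets, genes of the Hippo pathway, rose in 9 of 15 cases (9 adjusted over the list alone, 10 with the set term, 5 without E replicate 3 and 4 without M1 replicate 3), among them DLC1 and CRIM1. Their camera BH-adjusted p was 0.0461, with adjusted p = 0.523 with an estimated correlation and 0.0612 with the replicate number as a block, the form in which M1 and E libraries of one number varied together. That call also ended without E replicate 3, EM1 replicate 1, M1 replicate 2 or M1 replicate 3 (adjusted p = 0.0562, 0.0501, 0.0989 and 0.134).

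M1 differed from E in 6738 genes (edgeR, BH-adjusted p under 0.05), 3371 higher and 3367 lower. Among the extremes, the matrix protein gene MXRA5 (0.91 ± 0.26 TPM) and CAAP1 (5.49 ± 1.43) had no count in E. The protease inhibitor A2ML1, the cytochrome CYP4B1 and the zinc-binding glycoprotein AZGP1, at 6.65 ± 0.44, 14.2 ± 3.47 and 11.3 ± 3.83 in E, had no count in M1. With the set term 7165 genes were called (3562 higher, 3603 lower), 85.5% of the 6738 among them with the same sign, and higher genes made up 50% of the calls and 67.7% with TPM.

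M2, the other mesenchymal-named clone, lacked the epithelial adhesion molecule EPCAM (168 ± 4.01 TPM in E and 0.13 ± 0.05 in M2; edgeR, BH-adjusted p = 1.18e-11) and the basal keratin KRT5 (778 ± 46.9 and 0.36 ± 0.13). VIM rose to 2102 ± 552 and ZEB1 to 26.7 ± 6.25. Mesenchymal genes went both ways. COL6A3 rose to 143 ± 73.8 and the growth factor receptor PDGFRB from 0.02 ± 0.03 to 3.30 ± 1.25. DCN fell to 11.3 ± 5.15, the fibroblast protease FAP from 6.71 ± 0.90 to 0.04 ± 0.05, and CDH11 from 3.25 ± 0.33 to no count. The matrix gene TGFBI, which TGF-beta induces, rose from 63.1 ± 5.12 to 1161 ± 307. Of the 24 genes of the TGF-beta pathway list, though, 4 rose and 11 fell in M2 (5 and 12 with the set term). RUNX3 fell to 0.05 ± 0.05. CD44, a surface marker used for breast stem-like cells, measured 298 ± 51.3 against 491 ± 43.1 in E and did not pass the test (edgeR, BH-adjusted p = 0.102). It passed with the M2 and E libraries alone (adjusted p = 0.0383), with TPM (0.0167) and without Parental replicate 1 (0.034).

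Of the 30 epithelial genes 29 fell in M2 (29 adjusted over the list alone, 30 with the set term). The camera test gave a BH-adjusted p = 7.39e-17, and adjusted p = 0.0305 with an estimated correlation. Basal genes fell in 19 of 22 cases (19 adjusted over the list alone, 20 with the set term; camera, BH-adjusted p = 4.57e-09, and adjusted p = 0.173 with an estimated correlation). TP63, a master regulator of basal cells, rose from 1.00 ± 0.31 to 7.96 ± 5.78. Interferon response genes fell in 12 of 18 cases (13 adjusted over the list alone and with the set term, 8 with TPM; camera, BH-adjusted p = 0.00341, and adjusted p = 0.173 with an estimated correlation). IFI27 fell from 264 ± 58.6 to 8.51 ± 4.72. Blood, immune and endothelial markers lay lower (camera, BH-adjusted p = 0.0433, and adjusted p = 0.287 with an estimated correlation), a call that ended with the set term (0.0892). The mesenchymal list missed the threshold (camera, BH-adjusted p = 0.0542) and passed it with the set term (0.0308) and without M2 replicate 2 or 3 (0.0421 and 0.0336). Antigen presentation missed it (camera, BH-adjusted p = 0.116) and passed it with the set term (0.0448). With fry, which tests list genes without reference to other genes, both lists passed (BH-adjusted p = 0.000156 and 0.000573).

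M2 against E called 9564 of 18632 genes (edgeR, BH-adjusted p under 0.05), 4575 higher and 4989 lower. The forkhead transcription factor genes FOXI1 and FOXE1 stood at 20.1 ± 2.80 and 8.95 ± 0.87 TPM in E and had no count in the 3 libraries of M2. CAAP1 (18.4 ± 8.48) and MAGEA3 (17.6 ± 3.32), a cancer-testis antigen whose reads its close paralogs can share, had no count in E. With the set term 10313 genes were called (4902 higher, 5411 lower), 90.3% of the 9564 among them with the same sign, and higher genes made up 47.8% of the calls and 59.5% with TPM.

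Both M clones differed from E the same way in 4048 genes (edgeR, BH-adjusted p under 0.05 in each), 1885 higher and 2163 lower, where independent lists would share 827.7 and 901.6. The collagen receptor gene ITGA11 rose from 0.01 ± 0.02 TPM in E to 8.55 ± 4.34 in M1 and 5.23 ± 1.89 in M2. The cobalamin carrier TCN1, the tight junction gene TJP3 and the calcium pump ATP2C2, at 6.55 ± 2.10, 3.75 ± 1.51 and 1.66 ± 0.41 in E, had no count in either M clone. Of 10 genes the naming rule placed highest, CAAP1, PLAA, IFT74, TUSC1 and C9orf72 lie close together on chromosome 9 between bases 25676389 and 27573866 (hg38). These genes were also present in EM2, and near absent in E, EM1, EM3 and Parental. PLAA, for example, stood at 15.2 ± 2.08 in EM2, 19.3 ± 4.17 in M1 and 34.5 ± 8.85 in M2, and at 0.05 ± 0.05 or less elsewhere. With the set term both M clones shared 4155 genes (1915 higher, 2240 lower), 3360 of the 4048 among them. Higher genes made up 46.6% of the 4048 and 63.8% with TPM. Simulated unchanged groups against the E libraries, without a difference between library sets, shared no gene in 10 runs, though part of the excess can come from the shared controls.

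**Figure D4:**
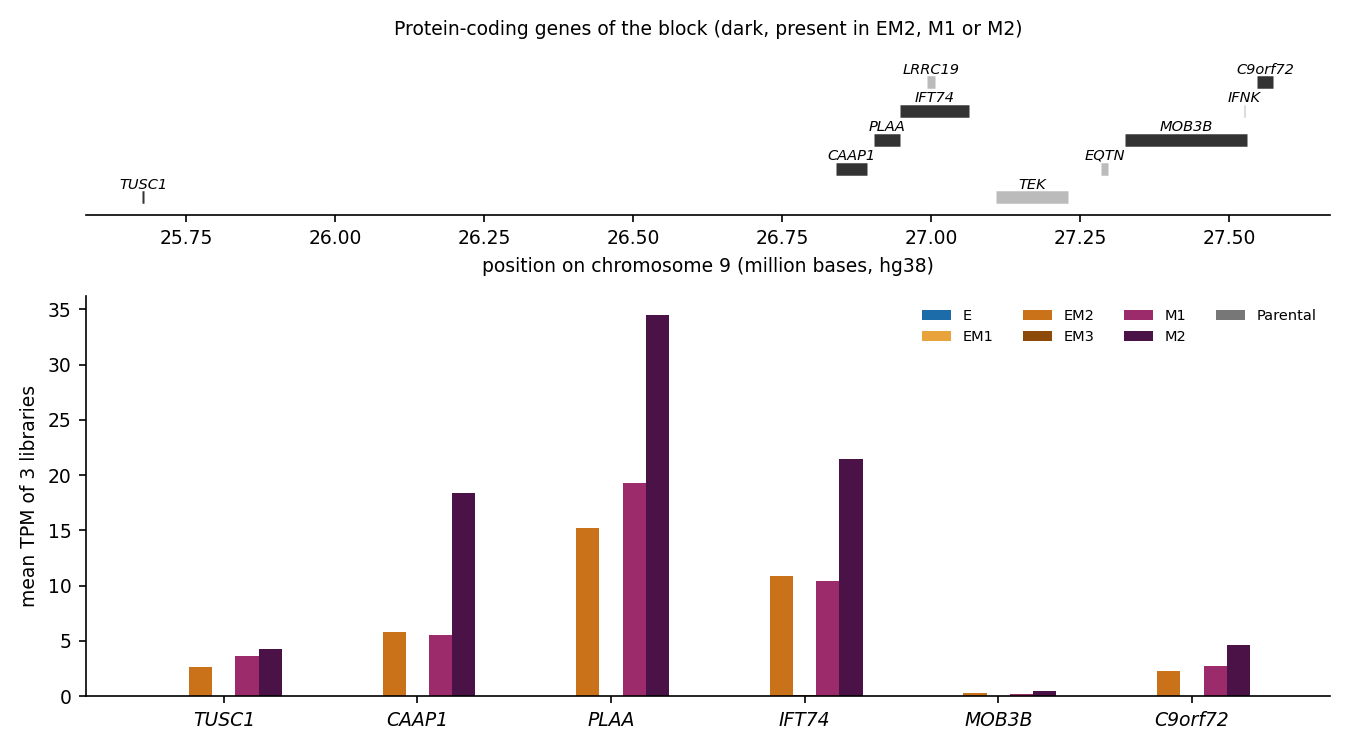
Upper panel, protein-coding genes of the chromosome 9 block at their base positions (hg38); lower panel, mean TPM of 3 libraries per line for the 6 genes present in EM2, M1 or M2. The 12 libraries of E, EM1, EM3 and Parental hold 48 counts of these 6 genes where 28327 would be expected at the rate of EM2.

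On the log2(TPM + 1) scale the median of genes with a mean TPM of at least 1 lay 0.22, 0.20, 0.28, 0.27 and 0.21 above E in EM1, EM2, EM3, M1 and M2. In the count fits, which cover more genes, it was 0.04, 0.01, 0.03, 0.03 and 0.01 (log2), and TPM tests call more genes higher. These medians differ in genes and scale. The TPM median lay 0.13 lower in E than in Parental and 0.14 higher in EM3 than in Parental. Lists without a camera call in any clone against E still held genes that changed. For core-binding factor camera gave BH-adjusted p = 0.116, 0.146, 0.166, 0.245 and 0.384 in EM1, EM2, EM3, M1 and M2, while fry called it in each, upward in EM1, EM2, EM3 and M1 (0.000787, 0.00219, 0.00234 and 0.000106) and downward in M2 (4.66e-06). Fry also called breast stem markers downward in EM3 and M2 (0.00662 and 0.0204) and breast lineage downward in EM3, M1 and M2 (0.0279, 2.56e-07 and 4.22e-07). It called the TGF-beta pathway upward in EM2 and M1 (0.0218 and 0.00153) and downward in M2 (0.00234), and the WNT pathway downward in M2 (3.78e-05). RUNX3 changed as above, while CBFB, its non-DNA-binding partner, measured 135 ± 3.83 TPM in E and 94.5 ± 7.06 to 131 ± 28.3 in EM1, EM2, EM3 and M1 without passing the edgeR test. Its direction in M1 flipped under TPM (log2 fold 0.27 by counts, -0.51 with TPM). For breast stem and surface markers camera gave 0.392, 0.606, 0.146, 0.929 and 0.768. Its members went both ways, with 2, 3, 2, 4 and 3 called higher and 3, 1, 4, 5 and 5 lower in EM1, EM2, EM3, M1 and M2. CD44 was higher in EM1 (1691 ± 191), EM2 (1465 ± 168) and M1 (2303 ± 420) than in E (491 ± 43.1), and CD24 was lower in M1 (3.38 ± 2.89 against 189 ± 19.0). For breast lineage and receptors camera gave 0.837, 0.756, 0.567, 0.0623 and 0.154 (0.0489, 0.0494, 0.0464 and 0.0482 in M1 without E replicate 2 or 3, M1 replicate 2 or M2 replicate 2). The luminal factor FOXA1 was lower in M1 (0.78 ± 0.19 against 9.22 ± 1.81). For the TGF-beta pathway it gave 0.542, 0.184, 0.28, 0.293 and 0.362, with the latency protein LTBP1 higher in EM2 (12.2 ± 3.30) and M1 (41.3 ± 8.94) than in E (1.48 ± 0.45). The WNT pathway gave 0.939, 0.777, 0.921, 0.837 and 0.353, and in M2 9 members were lower and 6 higher (14 and 6 with the set term), the secreted WNT modulator DKK3 among the higher (124 ± 53.8 against 0.18 ± 0.05). For cell stress it gave 0.962, 0.558, 0.664, 0.939 and 0.997; no member was called in EM1, EM2 or EM3 by edgeR in the reported fit, limma-voom or DESeq2, with 1, 0 and 0 at an unadjusted edgeR p under 0.05. In EM1 1 member was higher with the set term and without M2 replicate 2, and in EM2 1 was lower without EM2 replicate 3.

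Within the EM class, EM2 stood apart from EM1. HMGCS1 lay at 15.1 ± 4.52 TPM in EM2 and 240 ± 128 in EM1 (edgeR, BH-adjusted p = 9.83e-05) and SQLE at 19.6 ± 6.42 and 140 ± 43.3, while COL6A3 was higher in EM2 (49.3 ± 9.06 against 1.76 ± 0.45). The hydrolase CMBL (9.20 ± 2.4) had no count in EM1, and the X-linked gene ARMCX6 (5.12 ± 1.40 in EM1) and the meiosis gene HORMAD1 (6.21 ± 4.03) had no count in EM2. The contrast called 1516 genes (edgeR, BH-adjusted p under 0.05), 653 higher and 863 lower in EM2, 3177 with the set term (1428 higher, 1749 lower) and 617 with the EM1 and EM2 libraries alone. Without EM1 replicates 1 and 2 and EM2 replicates 1 and 3 the count was 983, 995, 883 and 1001.

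EM3 and EM1 were closest, with 69 called genes (edgeR, BH-adjusted p under 0.05), 32 higher and 37 lower in EM3. The transcription cofactor EYA4 stood at 3.33 ± 1.16 TPM in EM3 and 0.06 ± 0.05 in EM1, the matrix gene FBLN1 at 0.89 ± 0.15 and 0.12 ± 0.06, and creatine kinase CKB at 0.33 ± 0.13 and 4.65 ± 1.76 (edgeR, BH-adjusted p = 3.18e-05 for each). With the set term the count was 154 (72 higher, 82 lower), 1 when only the EM1 and EM3 libraries were fitted, and 0 within the long set alone by edgeR. In the long set 1096 genes had an unadjusted p under 0.05 (589 higher, 507 lower). By chance a share of 0.05 of all tested genes would reach that, so they do not count as differences found. EYA4, FBLN1 and CKB missed the threshold within the long set (log2 fold 5.70, 3.84 and -3.90, adjusted p = 0.122, 0.204 and 0.156). FBLN1 and CKB also missed it with the EM1 and EM3 libraries alone (adjusted p = 0.0575 and 0.0541). FBLN1 missed it with TPM too (limma-trend, adjusted p = 0.197). Its log2 fold of 0.76 there was taken on log2(TPM + 1), which shrinks the fold of a gene under 1 TPM. The 69 became 43, 45 and 41 without E replicates 1, 2 and 3, 34 and 35 without EM1 replicates 1 and 2, and 32, 40 and 25 without EM3 replicates 1, 2 and 3.

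EM3 against EM2 mirrored the first of these contrasts: HMGCS1 was higher in EM3 (194 ± 74.0 against 15.1 ± 4.52 TPM; edgeR, BH-adjusted p = 0.000276), as was IFI27 (68.9 ± 22.6 against 0.36 ± 0.27). ARMCX6 (8.45 ± 2.33) and HORMAD1 (6.47 ± 3.74) had no count in EM2, and TUSC1 (2.67 ± 0.44) and C9orf72 (2.26 ± 0.34) of the chromosome 9 block had no count in EM3. The contrast called 1255 genes (edgeR, BH-adjusted p under 0.05), 732 higher and 523 lower in EM3, 2536 with the set term (1456 higher, 1080 lower), 656 within the long set and 773 without EM2 replicate 1.

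The M clones differed from each other in 7674 genes (edgeR, BH-adjusted p under 0.05), 3538 higher and 4136 lower in M2, in 9984 with the set term (4745 higher, 5239 lower) and in 4570 within the long set. MMP13 (244 ± 53.4 TPM in M1), the chemokine CXCL6 (293 ± 102) and CDH11 (64.7 ± 9.29) had no count in M2, and the BMP antagonist GREM1 went from 1398 ± 623 to 0.08 ± 0.07. CXCL1 (2296 ± 183 against 0.46 ± 0.11), WNT5A (465 ± 55.3 against 4.43 ± 2.93) and DCN (2001 ± 384 against 11.3 ± 5.15) were lower in M2. The cancer-testis genes MAGEA2 (61.6 ± 7.23), XAGE1A (180 ± 24.1) and SPANXB1 (343 ± 136) had no count in M1; close paralogs can share their reads, so their levels are uncertain.

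Each clone was also set against the uncloned line to ask what cloning set apart; Parental lies in neither library set, so no set term could be fitted. E lay below Parental in VIM (13.8 ± 1.54 against 127 ± 54.0 TPM; edgeR, BH-adjusted p = 9.03e-06) and above it in the esterase CES1 (28.4 ± 3.86 against 0.10 ± 0.10) and in TIMP3 (3.13 ± 0.34 against a single count in the 3 libraries). It alone had no count of TRMT10B (1.39 ± 0.31 in Parental). E against Parental called 2040 genes (edgeR, BH-adjusted p under 0.05), 936 higher and 1104 lower; the count was 1067, 762 and 810 without E replicates 1, 2 and 3 and 1127 and 1136 without Parental replicates 2 and 3. EM1 differed from Parental in 374 genes (175 higher, 199 lower). VIM (706 ± 98.5) and SQLE were higher (140 ± 43.3 against 31.2 ± 13.3), and CMBL (1.46 ± 0.63 in Parental) and CRMP1 (0.57 ± 0.18) had no count in EM1. The 374 became 207, 230 and 211 without EM1 replicates 1, 2 and 3 and 197 without Parental replicate 2, and higher genes made up 46.8% of the calls and 67.2% with TPM. EM2 differed in 1024 genes (433 higher, 591 lower), with COL6A3 (49.3 ± 9.06 against 1.45 ± 0.27) and TUSC1 (2.67 ± 0.44 against no count) higher and HORMAD1 (5.44 ± 1.48 in Parental) without a count in EM2. Without EM2 replicates 1 and 3 and Parental replicate 2 the 1024 became 571, 657 and 637, and the share of higher calls was 42.3%, or 57.2% with TPM.

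EM3 differed from Parental in 689 genes (edgeR, BH-adjusted p under 0.05), 339 higher and 350 lower. Among them VIM (1255 ± 223 TPM against 127 ± 54.0), ZEB1 (3.38 ± 0.76 against 0.15 ± 0.09) and COL6A3 (25.1 ± 2.42 against 1.45 ± 0.27) were higher and the sialomucin PODXL2 lower (0.01 ± 0.01 against 2.45 ± 0.44). The 689 became 367, 448 and 353 without EM3 replicates 1, 2 and 3 and 414 without Parental replicate 2, and the share of higher calls was 49.2%, or 76.7% with TPM. M1 differed in 5052 genes (2436 higher, 2616 lower; 48.2% higher, or 60.3% with TPM). FOXC2, a forkhead factor of mesenchymal cells (10.3 ± 1.89), and CMTM2 (66.0 ± 4.70) were present in M1 and without a count in Parental, while A2ML1 (7.46 ± 1.07 in Parental) and TCN1 (23.2 ± 5.98) had no count in M1. M2 differed in 8567 genes (3968 higher, 4599 lower). The homeobox gene PKNOX2 stood at 179 ± 29.4 and the adhesion receptor ADGRF5 at 50.5 ± 10.5 in M2, with no count of either in Parental, and the myosin gene MYO5C (5.53 ± 1.06 in Parental) had no count in M2. Across other settings the counts against Parental reached 5238 for E and 7580 for M1, and spanned 59 to 1091 for EM1, 436 to 2448 for EM2 and 321 to 2426 for EM3 and 5505 to 10838 for M2.

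**Figure D5:**
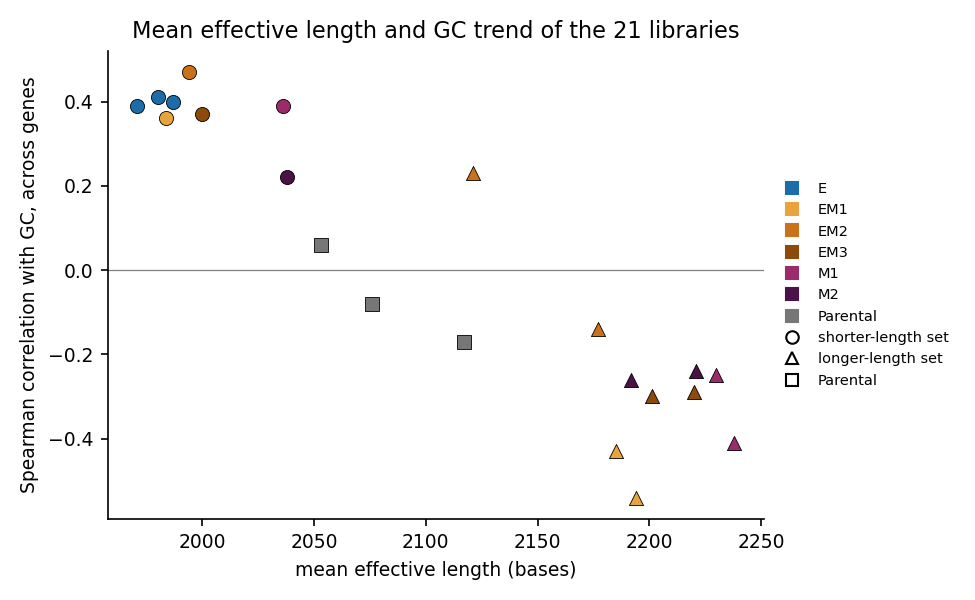
Mean effective length in bases (horizontal) against the Spearman correlation of each library with GC content across genes (vertical), coloured by line, with the library set as the symbol. The short set lies at 1971 to 2038 bases, the long set at 2121 to 2238 and Parental at 2053 to 2117.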

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

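Genes called in opposite directions against E in 2 clones, and called between the clones, were picked out as differences between groups. EM2 and EM1 held 58 such genes (24 higher in EM2, 34 lower), among them the T-box factor TBX3 and the X-linked genes ARMCX3, BEX1 and ARSD. EM3 and EM1 held 3 (2 higher in EM3, 1 lower), EM3 and EM2 held 44 (24 higher in EM3, 20 lower), and M2 and M1 held 612 (227 higher in M2, 385 lower), among them CXCL6 and MMP13. The tests of the 3 patterns below were chosen after the results were seen, and the counts under other splits of the libraries were planned before.

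The mean effective length of a library, which the main tests on counts do not use, split the clone libraries by a gap of 83 bases (second largest 56). The difference between short and long sets followed transcript GC content in each of the 5 clones with libraries in both sets (correlation 0.43 to 0.74 over 11110 genes), as GC bias between library preparations would produce. Library size was not excluded, because totals largely followed the set, although 5 of the 8 short-set totals lay within the range of the long set. The lowest short-set total was 41677476 counts (EM1 replicate 3). In the long set only EM2 replicate 1 (44709056) and M1 replicate 2 (46571768) exceeded it. Each also exceeded the short-set library of its own clone (42744372 and 42373975). The set is not the whole cause of the calls against E, since at least 79.1% of them were made again with the set as a term. E lies wholly in the short set. A biological cause, such as culture density at one harvest, was not tested.

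In the chromosome 9 block from TUSC1 to C9orf72, the 6 of 10 protein-coding genes that EM2, M1 or M2 expressed held 48 counts in the 12 libraries of E, EM1, EM3 and Parental where 28327 would be expected, which library size cannot give. Within the long set EM1 and EM3 reached at most 0.24% of EM2, so the library set does not explain it. Loss of the DNA predicts that no annotated gene of the block has 30 or more counts there, and 0 did. Silencing of the block predicts the same, and RNA cannot separate these explanations. The 0 was partly fixed in advance. TUSC1, CAAP1, MOB3B and C9orf72, which delimit the block, were chosen for at most 3 counts in each of E, EM1, EM3 and Parental. PLAA and IFT74 were not chosen so. In E, EM1, EM3 and Parental PLAA held 5, 1, 4 and 7 counts and IFT74 held 2, 1, 6 and 4. In EM2 PLAA and IFT74 held 3541 and 1508.

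In M2 alone 124 genes were absent that every other line expressed. Absent meant at most 3 counts over 3 libraries, and expressed meant at least 30 counts in each library. These genes held 173 counts in M2, summed. At the lowest other line's rate at least 94 counts were expected for each. The cutoffs made a high expected count certain, so it is not a separate test of library size. The highest number of such genes in any other line was 1. The genes lay on 20 chromosomes, and 19 further absences were shared by M2 and 1 other line. A further 46 genes were present in M2 and absent in all 6 other lines, which loss or silencing in M2 would not give. Loss, silencing or activation of many genes in this clone, or cells of another origin under the label, remain open; genotypes were not analysed here.

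Other splits of the libraries show what grouping alone can give. For each of the 15 contrasts 3 libraries against 3 have 10 splits, too few for a share under 0.05: in each only 1, the real one, reached its count, and the highest other gave 0 calls, except 4 in EM2, 1 in EM3 and 38 in M2 against Parental. Of 100 splits only the real 1 reached 1202 genes shared by all 3 EM clones (highest other 259, with the EM2 libraries in the place of E). The same held for 4048 shared by both M clones (highest other 3661, which kept the E libraries and mixed M1 with M2). It also held for 78 that set the EM clones apart (highest other 0). A random assignment of these libraries to lines would thus seldom reach these counts. The other splits mix libraries of unlike lines, which widens the spread within a group. Each clone is a single line, so the splits cannot exclude chance differences between clones. For the list tests 2 of 100 splits, the real one included, reached the real 39 calls. The highest, with 48, had 2 M1 libraries and 1 M2 library in the place of E. A split that mixed lines thus gave more list calls than the real one, so the splits do not bear out any single list call.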

How the results depend on the processing

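For the contrasts and shared genes, counts not given here stayed within 1.5 times the reported value. Of genes called both in the reported fit and in an alternative, 1 turned its sign (M2 against E, TPM). The side with more calls did turn: higher genes made up 54.9% of the calls in EM1 against E and 47.5% with limma-voom, and the TPM shares in the report lie above 50% where counts gave less. CBFB in M1 against E was the only named gene to reverse (log2 fold -0.51 with TPM). With the libraries of the 2 groups only, EM2 and EM3 against E gave 4267 and 5904, E, EM1, EM2, EM3 and M2 against Parental 5238, 59, 436, 321 and 5505, EM2 against EM1 617, EM3 against EM1 1, EM3 against EM2 759, M2 against M1 5046 and all 3 EM clones 2002. Without a low-count filter, E, EM1, EM2 and EM3 against Parental gave 3452, 1091, 1640 and 1404 and EM3 against EM1 241. The DESeq2 Wald test gave 3111, 841 and 1208 for E, EM1 and EM3 against Parental and 163 for EM3 against EM1. The replicate block gave 3716 for E against Parental and 1837 for all 3 EM clones, and ended no list call but those named in the report. With TPM, EM2 against Parental gave 661, EM2 against EM1 938, EM3 against EM1 31, EM3 against EM2 806 and EM clones apart 48. The set term gave 3177, 154, 2536 and 145 for EM2 against EM1, EM3 against EM1, EM3 against EM2 and EM clones apart. The long set alone gave 983, 0 and 656 for the 3 EM contrasts and 4570 for M2 against M1, with fewer libraries. Mean effective length as a covariate gave 1087, 2448, 2426 and 7580 for EM1, EM2, EM3 and M1 against Parental, 2635, 150 and 2091 for EM2 against EM1, EM3 against EM1 and EM3 against EM2, and 118 for EM clones apart. An estimated correlation kept 6 of the 39 list calls, while fry called 56, ended the proliferation calls and added 21. Counts of called list genes moved further, with single libraries left out and with TPM, as given beside them. Except for fewer libraries, the cause was not tested.

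Leaving out 1 library gave 1812 to 4640 for EM1, 1556 to 2980 for EM2, 1950 to 3754 for EM3, 5127 to 7299 for M1 and 8392 to 10065 for M2 against E. Against Parental it gave 762 to 2514 for E, 197 to 465 for EM1, 571 to 1177 for EM2, 353 to 822 for EM3, 3733 to 5514 for M1 and 7655 to 9061 for M2. It gave 883 to 1758 for EM2 against EM1, 25 to 77 for EM3 against EM1, 773 to 1436 for EM3 against EM2, 6679 to 8209 for M2 against M1, 656 to 1423 for all 3 EM clones, 3054 to 4362 for both M clones, 55 to 93 for EM clones apart and 35 to 41 for list tests. At these depths edgeR found 16.4% of simulated 2-fold changes, so an uncalled gene can still differ by 2-fold.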

Other observations

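The test in the next sentences was chosen after the result was seen. VIM stood at 127 ± 54.0 TPM in Parental and 13.8 ± 1.54 in E, which a share of mesenchymal-like cells in the parental culture could give. That level would need 12% EM2-like, 4.29% M1-like or 5.44% M2-like cells, and the chromosome 9 block, which those lines express, allows 0.497, 0.447 and 0.219% at the upper 95% bound, which covers counting error alone. Cells that express the block as these 3 clones do therefore did not account for the vimentin level of Parental. TUSC1, CAAP1, MOB3B and C9orf72 of the block were chosen partly for near 0 counts in Parental, which can lower that bound. PLAA and IFT74, not chosen so, held 7 and 4 counts in Parental. Cells like them in which the block is silent would leave no such counts, and RNA cannot exclude them. EM1 (706 ± 98.5) and EM3 (1255 ± 223) lack the block as Parental does, so a share of cells like them was not tested and stays possible.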
